A study of Mus musculus with 16 samples.

How the data were processed

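Genomic DNA from the tails of 8 C57BL/6 mice of one family, a father, a mother and 6 progeny, was measured by array comparative genomic hybridisation, in which a test DNA and a reference DNA carry different dyes and compete for the same probes. Each mouse was hybridised on 2 arrays with swapped dyes against the DNA of 1 reference male mouse (number 12) of the same colony, which gives 16 arrays. The array was a custom Agilent design for a second screening round, with probes placed densely around positions chosen in a first screen of the study. The first screen and the later TaqMan assays of the study were not used here. Samples were assigned to mice and dyes from the labels alone. The labels put the mice of this family in a line named as non-irradiated, while the series title speaks of males exposed to 1 mGy per day for 400 days, so mice were grouped only by their place in the family and no dose was compared.

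Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1 and a CGH protocol, and probe positions are on mm9. The deposited scanner files give processed intensity values for both channels that the software had background-subtracted and dye-normalized, median pixel intensity of the spot and its local background, and a log10 ratio of red over green. Further settings of the extraction are not given in the sources used here. A deposited value table holds log2 ratios of the same spots, and its normalization is not given in the sources used here. Set against the scanner log ratios, its columns correlated positively on the 8 arrays with mouse DNA in Cy3 and negatively on the 8 arrays with mouse DNA in Cy5, with the smallest correlation at 0.957 in size. By the dyes in the labels the deposited log2 table therefore runs as reference over mouse on every array, with medians from -0.0026 to 0.012, and its sign was turned before use as an alternative. Deposited log10 ratios were used only for this comparison.

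The main values were log2 ratios of the processed signals, turned to mouse over reference by the dyes in the labels. Control spots and spots marked as non-uniform or population outliers were left out, 82 to 159 of 120491 non-control spots per array, and no spot was saturated. Each array was centred on the median of its autosomal probes without loess or quantile normalization. Spots at the same position were averaged, which left 116451 positions, 116400 of them autosomal. The 2 arrays of a mouse were averaged to 1 value per mouse, so n counts mice. Between 99.8% and 99.9% of spots were well above background in both channels, with median raw signals of 748 to 1308 in green and 1232 to 2043 in red over median backgrounds of 38.5 to 44 and 68 to 73. The number of arrays per mouse limits the precision of each value. Arrays of one dye orientation from different mice correlated at 0.484 to 0.855 over autosomal probes, a value that includes the dye bias each probe has on every such array.

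Regions were called in each mouse with an interval caller written for this purpose in Python 3.11.15 with numba 0.67.0. Autosomal probes were divided into 3979 runs at gaps over 100 kb. An interval needed at least 3 probes, a mean log2 ratio of at least 0.25 in size with the same sign on both dye-swapped arrays, and a score of at least 6, where the score is the size of the mean times the square root of the number of probes over the robust SD of the mouse. Of the intervals of a run that met every criterion the one with the highest score was taken, and the search went on to its left and right. Overlapping calls of one direction were merged over mice to regions. A mouse carried a region when its mean over the merged region passed 0.25 in that direction on both arrays. The same caller was run on a dye-bias track, in which one orientation had its sign turned, to count calls made from dye effects. The score there used the robust SD of that track, which was larger than that of the dye-swap mean. Short intervals therefore needed a larger mean on it. On simulated values with the spread of the father or of progeny 1, the caller found 80% and 86.7% of implanted regions of 3 probes at -0.35, and 100% of those with 10 or 50 probes at -0.35 or of any size at -0.8, with 0 false calls. The simulated noise was independent between probes. Of the real spacings, 33.8% are under 60 bp, the median probe length, so neighbouring probes partly read the same bases and scores of short regions may be too high. The size of this effect was not measured.

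Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the dye-swap means, with Benjamini-Hochberg adjustment at 0.05. One test set the mean of the 8 mice against 0, the level of the reference, and one set 6 progeny against 2 parents. The first leaves out the spread of the reference, which is 1 DNA, and mice of one family are not independent draws from the colony. On simulated values, 99% of probes shifted by 0.25 in all mice were recovered, and 63% of those shifted by 0.25 in all 6 progeny, with 13 false calls in each comparison over 116276 probes. Changes in only some of the progeny were not simulated. Shares of carriers among progeny have exact Clopper-Pearson 95% intervals and exact two-sided binomial tests against 50%, computed with scipy 1.17.1.

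The tests, their alternatives and the rule for named regions were fixed before the data were examined. Named were the 25 regions with the highest score, up to 15 progeny-only regions and up to 15 regions shared by a parent and progeny by score, and up to 5 probes of each sign from each limma test that were past the threshold with 1 sign in all mice, or in all progeny for the comparison of progeny with parents. The alternatives were normexp background correction with an offset of 50 on median signals, since mean signals were not used here, and loess within arrays. Others were a filter on dim probes, flagged spots kept, repeated spots kept apart, other thresholds of the caller, single dye orientations, the deposited table, each progeny mouse left out, and other limma models. The planned tests of gene families and the alternative that corrects for GC content were not run. The reference table at hand is on GRCm38.p6 rather than mm9, and the arrays carry no gene names, so regions are given by position only, without gene, exon or intron.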

Results

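The series followed DNA copy number in a family of C57BL/6 mice, an inbred laboratory strain, to ask which aberrations in progeny were present in their parents. Tail DNA of a father, a mother and 6 progeny was compared with DNA of 1 reference male on 16 two-colour arrays, 2 per mouse with swapped dyes. The arrays held 120491 non-control spots at 116451 positions, 116400 autosomal, 48 on the X and 3 on the Y chromosome, with a median spacing of 97 bp. Probes lay densely around positions chosen in a first screen, with autosomal probes in 3979 runs parted by gaps over 100 kb. The regions below are therefore no survey of the whole genome. All log2 ratios below are mouse over reference, means of both arrays of a mouse, with positions on mm9. A heterozygous loss would give a log2 ratio of -1 and a heterozygous gain of 1 copy 0.585 if probes responded in full. Each mouse is 1 DNA sample, so values of a single mouse carry the SD over the probes of a region.

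The sex chromosome probes were read first, as a check of the labels against a male reference. The father had a median log2 ratio of 0.014 over 48 X probes and -0.011 over 3 Y probes. The mother had 0.95 on X and -3.63 on Y. Progeny 1 had -0.015 on X and 0.053 on Y. Progeny 2 to 6 had X medians of 0.93, 0.97, 0.98, 0.91 and 0.94 and Y medians of -3.41, -4.11, -3.86, -3.43 and -3.48. The parents' values went with their labels, and the direction of the ratios was the one the dyes gave. Progeny 1 read like the father and progeny 2 to 6 like the mother, so by these probes progeny 1 was male and the others female.

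What the family carried at the positions on the array was read first from the long regions. Of 636 called autosomal regions, 17 held at least 10 probes, and the 5 described next lay within 0.023 of 0 in every mouse that did not carry them. On chromosome 4, positions 101109394 to 101270967 (161.574 kb, 1108 probes) were gained in the father at 0.53 ± 0.11 (SD over probes), in progeny 1 at 0.50 ± 0.12 and in progeny 3 at 0.53 ± 0.11. The mother and the other 4 progeny lay between -0.0083 and 0.015. The carriers averaged 0.52 ± 0.014 (SD, n = 3 mice), against -0.0014 in the 5 others. The 15 probes before and the 15 after the region had means from -0.049 to 0.046 in the 8 mice.

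Losses shared with progeny were seen in each parent. On chromosome 2, positions 130646358 to 130650566 (4.209 kb, 25 probes) were lost in the father at -0.84 ± 0.23 (SD over probes) and in progeny 2, 3, 4 and 5 at -0.78, -0.83, -0.79 and -0.73, with a carrier mean of -0.79 ± 0.045 (SD, n = 5). The mother and progeny 1 and 6 had means of 0.0019, -0.0089 and 0.023. On chromosome 13, positions 74607886 to 74705673 (97.788 kb, 53 probes) were lost in the mother at -0.65 ± 0.21 (SD over probes) and in progeny 1, 2, 3 and 4 at -0.57, -0.60, -0.67 and -0.66, with a carrier mean of -0.63 ± 0.043 (SD, n = 5). The father and progeny 5 and 6 lay between -0.0065 and 0.00, and the 15 probes before the region still had means of -0.086 in the mother and -0.12 in progeny 2. On chromosome 3, positions 25421508 to 25454249 (32.742 kb, 14 probes) were lost in the mother at -1.30 ± 0.98 (SD over probes) and in progeny 2 to 6 at -1.29 to -1.44. The father was at 0.0035 and progeny 1 at -0.0016, and these were also the mice with X and Y probes near 0. In that region the probes differed widely, and the lowest reached -3.90 in the mother and -4.12 in progeny 2.

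**Figure D1:**
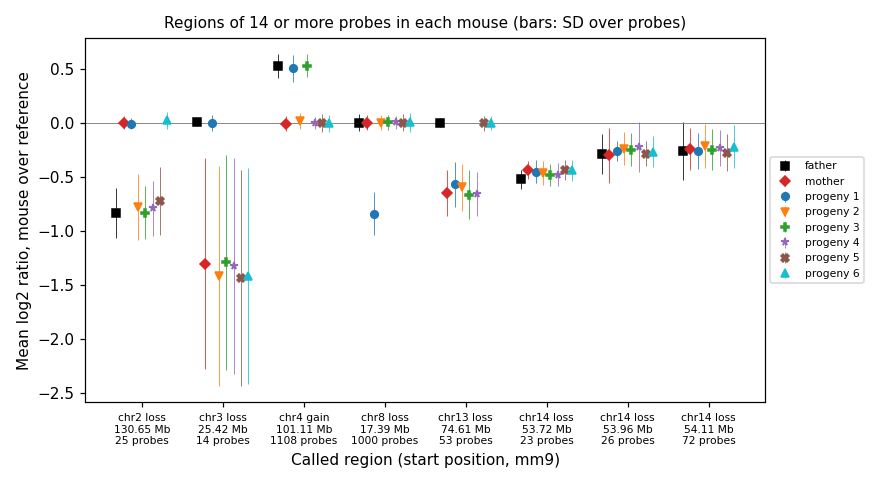
Mean log2 ratio, mouse over reference, of each of the 8 mice (symbols) over every called region of 14 or more probes, with bars for the SD over probes. Carriers of the chromosome 4 gain sit near 0.52 and the chromosome 8 loss appears in progeny 1 alone at -0.84, while the 3 chromosome 14 regions lie below 0 in all mice.

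Transmission was compared with an even chance. The chromosome 4 gain of the father was carried by 2 of 6 progeny (33.3%, 95% exact interval 4.33% to 77.7%), which did not differ from 50% in an exact two-sided binomial test (p = 0.6875). The chromosome 2 loss of the father and the chromosome 13 loss of the mother were each carried by 4 of 6 progeny (66.7%, 22.3% to 95.7%, exact p = 0.6875). The chromosome 3 loss of the mother was carried by 5 of 6 (83.3%, 35.9% to 99.6%, exact p = 0.2188), but its carriers were the 6 mice with Y medians of -3.41 or lower, so autosomal transmission is not established by this share. Its lowest probe reached -3.90 in the mother and -4.12 in progeny 2, far below the -1 of a heterozygous loss. With the father at 0.0035, progeny 2 to 6 would have kept a paternal copy. Inheritance of 1 lost autosomal copy from the mother is therefore argued against. A share of 50% assumes a heterozygous parent, so this test has no clear meaning for that region. With 6 progeny the smallest p this test can give is 0.03125, so only a region carried by all or by no progeny could pass.

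Progeny-only regions address the study's question of aberrations absent from the parents. The longest was a loss on chromosome 8, positions 17385503 to 17492307 (106.805 kb, 1000 probes), carried by progeny 1 alone and called there as 1 interval of 999 probes. Progeny 1 had a mean of -0.84 ± 0.20 (SD over probes), a ratio of 0.557 to the reference, with -0.89 on the array with mouse DNA in Cy5 and -0.80 on the array with mouse DNA in Cy3. The father was at 0.0018 ± 0.078 and the mother at -0.00099 ± 0.069, and the other 5 progeny lay between -0.00071 and 0.0041. The probes ending at 17382294 and starting at 17499180 flank the region, and the 15 probes on each side had means of 0.011 and 0.035 in progeny 1. Inside the region the caller also found intervals of 3 probes, 2 in the father at -0.37 and -0.28, 1 in the mother at -0.29 and 1 in progeny 5 at -0.31, the last 2 at the same 177 bp. The loss in progeny 1 had the highest interval score of all 636 regions. The score rises with the number of probes, and probes were placed densely around positions chosen in a first screen. This rank therefore depends on where the array was tiled.

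**Figure D2:**
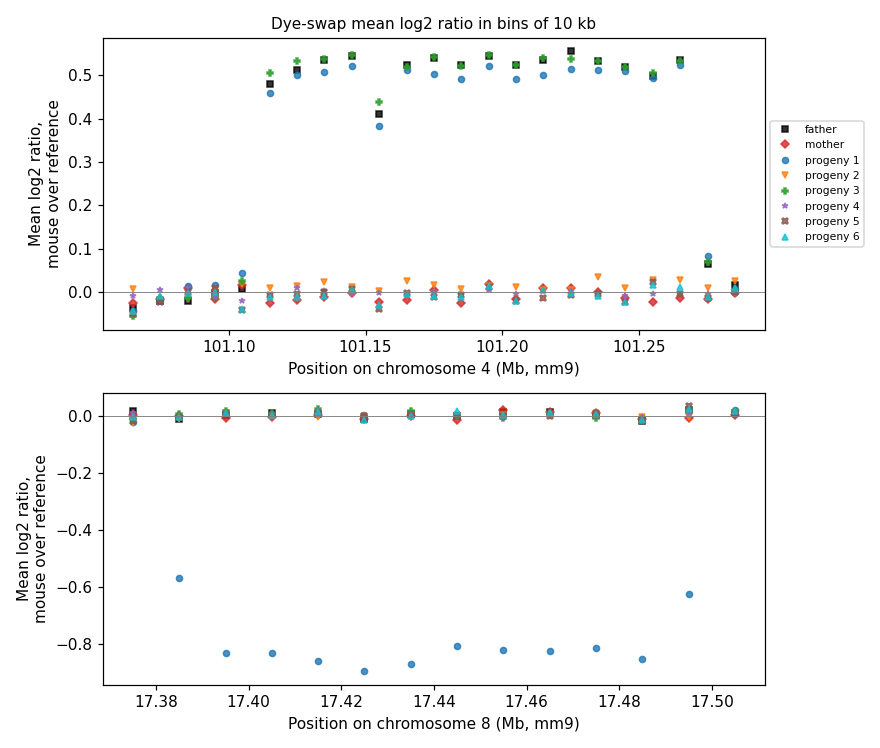
Mean log2 ratio, mouse over reference, in bins of 10 kb along chromosome 4 (top) and chromosome 8 (bottom) against position in Mb (mm9), with one symbol per mouse. The father and progeny 1 and 3 are raised over the chromosome 4 region, whose probes average 0.53, 0.50 and 0.53, and progeny 1 alone is lowered over the chromosome 8 region, at -0.84, where the other 7 mice lie between -0.00099 and 0.0041. Bins with fewer than 3 probes are not drawn.

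In all, 240 regions were called in at least 1 progeny mouse and carried by neither parent, but in 67 of them no progeny mouse carried the merged region either, which leaves 173 with a progeny carrier. Of the 240, 8 held 10 or more probes. In 89 a parent had itself been called within the merged region, and in 210 at least 1 parent had a mean of 0.1 or more in size in the direction of the call. With both parents required to lie below 0.1 in that direction, a bound set after seeing the data, 30 regions were left, 3 of them with 10 or more probes. These were the chromosome 8 loss, a loss on chromosome 13 at 117195827 and a loss on chromosome 14 at 93754028, and over the last 2 progeny 1 and 2 had 0.27 to 0.34 and progeny 3 to 6 were all below 0. Of the 15 progeny-only regions named by score, 12 held 3 to 5 probes, 8 called as gains and 4 as losses. Under normexp background correction 3 of these gains turned sign, on chromosome 2 at 70084140 (0.47 to -0.036) and 70085845 (0.30 to -0.046) and on chromosome 4 at 30874313 (0.39 to -0.072), and the loss on chromosome 4 at 30874364 went from -0.50 to -0.060. In 3 of the 4 losses a parent lay below every progeny mouse. On chromosome 11 at 41780710 the father had -0.43 and the lowest progeny mouse -0.36, on chromosome 15 at 55021652 the father had -0.38 against -0.34, and on chromosome 4 at 114585691 the mother had -0.34 against -0.32. The last comparison depends on the dyes, with -0.14 on Cy5 and -0.55 on Cy3 in the mother and -0.15 and -0.49 in progeny 6, and the father and progeny 1 lay near 0 there, at 0.011 and 0.033. In 0 of the 8 gains did a parent lie above every progeny mouse. Another of the 15, on chromosome 14 at 53964671 to 53991911 (26 probes), had -0.29 in the father and -0.30 in the mother against -0.22 to -0.29 in the progeny. It was called in all 8 mice and carried by none, since every mouse missed 0.25 on its Cy5 array. The last was a loss on chromosome 14 at 93754028 to 93761796 (13 probes), called where progeny 3 and 5 had -0.29 and -0.36 while progeny 1 and 2 both had 0.27. Progeny 4 and 6 had -0.20 and -0.12, so the progeny split here by scan day, with progeny 1 and 2 on day 1 and progeny 3 to 6 on day 2. Under a minimum of 5 probes the count was 123, with a minimum mean of 0.4 it was 69, with 0.15 it was 511, and with only one dye orientation 137 (Cy5) or 134 (Cy3).

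Regions shared by a parent and progeny numbered 278, of which 152 were carried by the father and not the mother, 24 by the mother and not the father, and 102 by both. Of all 636 regions, 607 held 3 to 6 probes. Over the 552 losses among these the median was -0.34 in the father and -0.21 in the mother. The split therefore does not compare transmission from the 2 parents. Among the 25 regions with the highest scores, 17 were losses of 3 to 5 probes and 86 to 1202 bp, and over these 17 the mean log2 ratio was -0.94 ± 0.21 (SD over regions) in the father, -0.73 ± 0.16 in progeny 1, -0.65 ± 0.14 in progeny 5, -0.58 ± 0.12 in progeny 6, -0.54 ± 0.096 in the mother, -0.39 ± 0.091 in progeny 3, -0.28 ± 0.080 in progeny 2 and -0.095 ± 0.065 in progeny 4. The highest-scoring of them lay on chromosome 18 at 69996671 to 69996866, with -1.31 in the father and -0.57 in the mother. The next were on chromosome 12 at 107492979 to 107493069, with -1.26 and -0.67, and on chromosome 4 at 139228263 to 139228348, with -1.21 and -0.62. The count of shared regions was 91 under a minimum of 5 probes, 119 with a minimum mean of 0.4 and 520 with 0.15.

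The number of calls differed widely between mice. The caller found 447 intervals in the father, 232 in the mother, and 356, 77, 161, 51, 401 and 339 in progeny 1 to 6. Losses made up 445 of the father's calls and 25 of the 51 calls in progeny 4. The same caller found 11 to 27 intervals per mouse on the dye-bias track, with 27 in progeny 4 beside its 51 calls. In progeny 4 the robust SD used in the score was 0.114 on that track and 0.045 on the dye-swap mean. The counts thus rest on unlike limits and are not a matched comparison. Over the family, 572 regions were losses and 64 gains, and 607 of 636 held 3 to 6 probes, with a median length of 317 bp for these. Requiring 10 probes and 1 kb, an alternative added after seeing the data, left 15 regions, 7 progeny-only and 8 shared by a parent and progeny. Of the 7, those on chromosome 5 at 10725735 and 107091206 and on chromosome 14 at 53964671 and 54073238 were also called in both parents. Those on chromosome 13 at 117195827 and on chromosome 14 at 93754028 split the progeny by scan day. The remaining one was the chromosome 8 loss. The total was 312 with at least 5 probes, 275 with a mean of at least 0.4 and 1191 with 0.15.

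**Figure D3:**
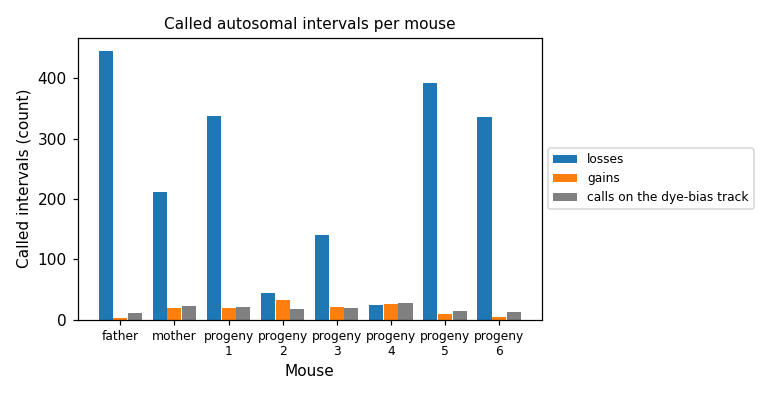
Number of called autosomal intervals per mouse (count on the vertical axis, from 0), as losses, gains and calls on the dye-bias track. Losses range from 25 in progeny 4 to 445 in the father, while the dye-bias track, scored with its own larger robust SD, gave 11 to 27 calls in each mouse.

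Dye-swap agreement shows only the part of the technical error that differs between the 2 arrays of a mouse. The 2 orientations of a mouse correlated across autosomal probes at -0.47 to 0.051, where probes are not independent replicates. The robust SD of the dye-swap mean was 0.051 in the father, 0.056 in the mother and 0.045 to 0.069 in the progeny, against 0.11 to 0.13 for the dye bias.

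Regions lost or gained in all 8 mice were counted apart, since every array shares the 1 reference DNA. All mice had calls in 4 regions, each on chromosome 14, but only 1 was carried by all of them, a loss on chromosome 14 at 53724567 to 53764803 (40.237 kb, 23 probes), with -0.46 ± 0.030 (SD, n = 8 mice) and a range from -0.52 in the father to -0.44 in the mother. A further region on chromosome 14, at 54108715 to 54314573 (205.859 kb, 72 probes), was lower in all mice at -0.25 ± 0.022 (SD, n = 8), although only the father and progeny 5 passed 0.25 on both arrays. The count of regions carried by all mice was 9 with either dye orientation alone, 10 without progeny 4 and 0 with a minimum mean of 0.4.

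**Figure D4:**
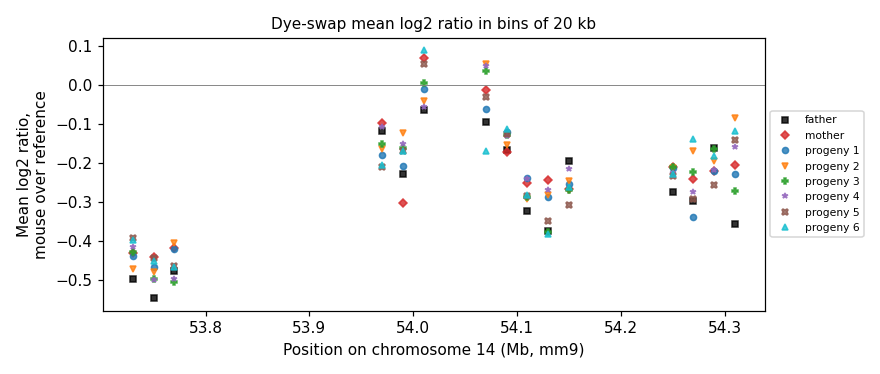
Mean log2 ratio, mouse over reference, in bins of 20 kb along chromosome 14 against position in Mb (mm9), with one symbol per mouse. All 8 mice lie below 0 over the region at 53724567 to 53764803, which averages -0.46, and over the region at 54108715 to 54314573, which averages -0.25; bins with fewer than 3 probes are not drawn.

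Over single probes, all mice against the reference gave 7805 of 116276 probes past the threshold in limma, 1898 higher and 5907 lower than the reference. The shifts were small, with a median size of 0.12, and 6436 of the 7805 were under 0.25. Of the 7805 probes, 1457 lay in called regions. Among the 132 probes of the chromosome 14 intervals of 10 or more probes between 53724567 and 54314573, 100 were past the threshold. These intervals were called from low values in the same mice, so that share is no separate support. Among probes past the threshold with 1 sign in all 8 mice, the lowest mean was at probe A_67_P00760264 (chromosome 3, 132549431 to 132549490), at -1.62 ± 0.27 (SE, limma adjusted p = 0.0055), with -1.96 in the mother and -0.010 in the father. Probe A_67_P11828408 (chromosome 3, 25428636 to 25428695) followed at -1.52 ± 0.26 (SE, limma adjusted p = 0.0063). The next 3, on chromosomes 9, 11 and 16, were A_67_P01905669, A_67_P07496476 and A_67_P08568204 at -1.46, -1.43 and -1.10, and at all 5 the father and progeny 1 were nearest to 0. Under the same limits the highest mean was at probe A_67_P17640459 (chromosome 12, 3628367 to 3628412), at 0.47 ± 0.092 (SE, limma adjusted p = 0.011), with values from 0.059 in the mother to 0.97 in progeny 4. Probes A_67_P05602880, A_67_P00943857, A_67_P01641285 and A_67_P02663347, on chromosomes 5, 4, 7 and 13, followed at 0.46, 0.45, 0.43 and 0.42, positive in all 8 mice. The one on chromosome 4 lies in the gain of the father and progeny 1 and 3, which had 0.64, 0.74 and 0.91 there against 0.11 to 0.38 in the other mice. The count was 4592 with slide as a random block, 12954 with the 16 arrays as units, a dye term and mouse as a random block, and 10888, 4993, 4606 and 4640 without progeny 2, 3, 5 and 6. In the fit of 16 arrays the correlation within mice was estimated at -0.044, so both arrays of a mouse count about as separate replicates.

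Progeny against parents gave 0 probes past the threshold in limma, with a smallest adjusted p of 0.5367 and 10306 of 116276 probes at an unadjusted p under 0.05. This contrast of group means reads changes common to the progeny. It cannot exclude changes in single mice, since the chromosome 8 loss of progeny 1 gave no probe past the threshold either. Sex was also unevenly spread, as progeny 1 alone of the progeny read as male. Both parents lay on slide 1 and the progeny on slides 2 to 4, and scan day 1 held both parents with progeny 1 and 2. The count was 0 with slide as a random block, where 6573 probes had an unadjusted p under 0.05, 0 with scan day as a block, where 18365 probes had an unadjusted p under 0.05, and 0 within scan day 1, where 11170 did.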

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

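In this part the tests of the chromosome 8 loss and of the losses tracking the father and progeny 1 were chosen only after those values had been seen. Of 55 values compared over the 6 progeny, 5 had 1 mouse far from the other 5, and progeny 1 was that mouse each time. Chance alone gives about 1 in 20 for values not chosen by their size, but 46 of the 55 were regions picked for score, class or length, so that share is no yardstick here. The X, Y, chromosome 3 and chromosome 4 values below repeat 1 split of the mice, that of sex as read from the X and Y probes. Progeny 1 had an X median of -0.015, where the others had 0.91 to 0.98, and a Y median of 0.053, where the others had -4.11 to -3.41. Its mean over the chromosome 3 region at 25421508 was -0.0016 against -1.44 to -1.29, and over the chromosome 4 loss at 114585691 it was 0.033 against -0.32 to -0.27. That last value was the mean of 0.31 on its Cy5 and -0.25 on its Cy3 array, and the mean of the 6 mice called there was -0.097 on Cy5 and -0.50 on Cy3 arrays. The father was at 0.011 and the mother at -0.34 over this region, so the mice split as on chromosome 3. The mean of progeny 1 over the chromosome 8 region at 17385503 was -0.84, against -0.00071 to 0.0041.

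The chromosome 8 loss of progeny 1 covered 1000 probes, over which the other 7 mice lay between -0.00099 and 0.0041. A fault of 1 array or 1 dye is argued against, since 96.5% of its probes lay below -0.25 on both dye-swapped arrays of progeny 1. The same loss in the tail DNA of a parent is argued against too, since the lower of both parents' means over the region was -0.00099. The 2 arrays share 1 DNA extract and 1 slide, and germ cells were not measured, so a fault of that extract and a loss carried by part of a parent's germ cells stay open. A loss that arose in a germ cell or in the early embryo is a candidate explanation as a hypothesis only, and no group of the design tests it.

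Losses seen in the mother and progeny 2 to 6 but not in the father and progeny 1 recurred on several chromosomes. Among all 28 pairs of mice, autosomal probes were counted at which the pair lay within 0.2 of 0 and the other 6 mice at or below -0.5, and the pair father and progeny 1 had 22 such probes on 8 chromosomes while the highest other pair had 2. Separate autosomal losses on each chromosome are argued against, since the 5 other pairs of the father with 1 progeny mouse had such probes on 0 chromosomes. Probes that also bind sequence on the Y chromosome may account for the pattern, because the father and progeny 1 were the mice with Y probes near 0 among the 8. In the chromosome 3 region at 25421508, a loss of 1 autosomal copy inherited from the mother is argued against. The father was at 0.0035 there, so progeny 2 to 6 would have kept a paternal copy and stayed near -1 or above. Their means were -1.29 to -1.44, and their lowest probes were at -4.00 to -4.12. The probe sequences were not aligned to a genome, so binding to Y sequence stays a hypothesis, and this region is open to it.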

How the results depend on the processing

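Of the alternatives in this part, the limits on region length and on the parents and the scan day fits were chosen after seeing the data. No paired analysis was possible because the father, the mother and the progeny share only the replicate number 1. The GC correction and the gene family tests were not run, since no mm9 sequence or annotation was used here. Called regions numbered 636, and 312 with at least 5 probes, 275 with a mean of at least 0.4, 1191 with 0.15 and 15 with 10 probes and 1 kb. Progeny-only regions numbered 240, and in the same order 123, 69, 511 and 7, with 137 and 134 from the Cy5 and Cy3 orientation alone and 30 with both parents below 0.1 in the direction of the call. Several of the 7 were also called in both parents. Shared regions numbered 278, and 91, 119, 520 and 8. Regions carried by all mice numbered 1, and 0 with a mean of at least 0.4 and 9 and 9 from the single orientations, and leaving out each progeny mouse gave 1 to 10, the latter without progeny 4. All mice against the reference gave 7805 probes, 4592 with slide as a random block, 12954 (4572 higher) with the 16 arrays, a dye term and mouse as a block, and 4606 to 10888 with each progeny mouse left out. Stricter or looser criteria move the region counts by construction, and the cause of the other shifts was not tested. Every other alternative kept these counts within 1.5 times, and progeny against parents stayed at 0 throughout. Of the 38 named regions, 3 short progeny-only gains turned sign under normexp, on chromosome 2 at 70084140 (-0.036) and 70085845 (-0.046) and on chromosome 4 at 30874313 (-0.072), and the cause was not tested. Another 9 named regions moved beyond their spread under normexp, among them the chromosome 11 loss at 53696498 from -0.68 to -0.19, the progeny-only chromosome 4 loss at 30874364 from -0.50 to -0.060 and the chromosome 15 loss at 55021652 from -0.33 to -0.21. The spread was the SD over carriers, or over callers without any carrier, and over probes where only 1 mouse was used. It was 0.0030 for the chromosome 12 gain at 3628095 and 0.58 for the chromosome 2 gain at 70084140. The count of moved regions therefore mixes unlike limits. The chromosome 4 loss at 114585691 went from -0.30 to -0.097 on the Cy5 and -0.50 on the Cy3 arrays. Over 5 alternatives the chromosome 8 loss ranged from -0.89 to -0.80, the chromosome 4 gain from 0.48 to 0.56, the chromosome 2 loss from -0.82 to -0.78, the chromosome 13 loss from -0.64 to -0.62 and the chromosome 3 loss from -1.43 to -1.36. On chromosome 14 the loss at 53724567 ranged from -0.50 to -0.43, at 53964671 from -0.31 to -0.22 and at 54108715, over its 2 carriers, from -0.28 to -0.23, the latter 2 under 0.25 in size with normexp and with loess. Although 99.8% or more of spots were well above background, this does not show how far signal strength bears on the shifts under normexp.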

Other observations

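On chromosome 14 all 8 mice stood below the reference within called intervals. Over the 132 probes of 4 intervals between 53724567 and 54314573 the mean log2 ratio was -0.28 ± 0.018 (SD, n = 8 mice), from -0.31 in the father to -0.26 in progeny 2. The intervals differed in depth, with -0.46 over the first and -0.25 over the last, and the levels lay well short of the -0.84 of the chromosome 8 loss in progeny 1. They did not form 1 unbroken stretch. The 15 probes after the interval at 53964671 had means from -0.14 to 0.081 in the 8 mice.

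A second kind of region moved both ways. There were 18 overlaps between a region called as a gain in some mice and a region called as a loss in others. On chromosome 13 at 117195673 to 117196841 (12 probes) the mother, progeny 1 and progeny 2 had 0.35, 0.34 and 0.36, the father had 0.02, and progeny 3 to 6 had -0.23, -0.07, -0.30 and -0.06. This goes with the scan day among the progeny, since progeny 1 and 2 were scanned on day 1 with both parents and progeny 3 to 6 on day 2. In a count added after seeing this, progeny 1 and 2 lay above 0 and progeny 3 to 6 below 0 in 10 of the 18 overlaps, while none of the other 14 pairs of progeny stood apart from the remaining 4 in that way. Scan day and slide go together here, the father and mother differ within 1 slide, and the cause stays open.

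The short losses were graded in a similar order across mice. In the tests of this pattern, the rank agreement of the progeny, its shuffled draws and the shared weights were chosen only after the pattern had been seen. Over 552 losses of 3 to 6 probes the median log2 ratio was -0.34 in the father, -0.31 in progeny 5, -0.28 in progeny 1 and in progeny 6, -0.21 in the mother, -0.19 in progeny 3, -0.11 in progeny 2 and -0.065 in progeny 4. Kendall's W of the 6 progeny was 0.702, and at most 0.153 in 1000 draws that shuffled the progeny once per chromosome. Losses inherited independently between chromosomes would give a low W. But the regions were called from low values in these same mice, and the draws did not repeat the calling. Part of the agreement may come from that choice, so W does not settle the question. The test of dim spots does not decide. The median log2 reference signal of these probes was 9.78, against 10.24 over all autosomal probes. It stood at the 33.5th percentile of autosomal probes (95% bootstrap interval over regions 30.7 to 36.1). That lay above the limit set beforehand for dim spots, but these probes were still dimmer than the typical probe. A factor of each mouse's DNA or arrays that acts on the same probes everywhere may account for much of the grading, since weights of the mice taken from odd chromosomes explained 75.02% of the differences between mice on even chromosomes, as a sum of squares. That share was first computed with the mean of each region kept, which gave 93.7%, and the means were removed only after that share was seen. The choice of regions from these same mice enters both shares. What the factor of each mouse is was not measured. Each of the 4 slides held 2 mice. The father lay below the mother on their slide, and progeny 1, 3 and 5 lay below progeny 2, 4 and 6 on theirs. The cause of this order within slides was not tested.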
